A study of Mus musculus with 9 samples.

How the data were processed

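RNA was measured by sequencing in the livers of 9 male C57BL/6 mice, in 3 groups of 3. Per the labels, the young mice were 8 weeks old. Both old groups were 20 months old and had been injected at 14 months with adeno-associated virus 9, a gene delivery vector, by tail vein and into the subcutaneous fat. The old control virus carried a negative control short hairpin RNA, and the other virus carried a short hairpin RNA against Fabp4. The labels describe the tissue as liver, while their RNA extraction text names NRVMs, the usual abbreviation for neonatal rat ventricular myocytes.

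Reads were aligned to the mouse genome GRCm38.p6 with HISAT2, per the submitters' processing notes. The counting program, its strand setting, the annotation release and the gene lengths are not given in the sources used here. The deposited count table holds whole read counts per Ensembl gene, with no scaling, for 54532 genes and 9 libraries. The deposited FPKM table holds fragment counts scaled by the authors to gene length and library size (FPKM), for the same genes and columns. The number of columns that matched no sample or group was 0. A column named Y2 stands where the labels list young mice numbered 1, 4 and 5. It was placed in the young group by its letter, with no animal number, and is called the unnumbered young library here.

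Both tables were checked against each other on 10483 genes with at least 20 counts. In 8 columns the FPKM was a fixed multiple of the count, within a relative tolerance of 0.001, for 100% of these genes. In the unnumbered young column this held for 0.229% of the genes, so the 2 tables hold different values under that name. The reads behind that FPKM column were recovered by scaling it back to whole reads. Of 17877 values tested, 100% were whole within 0.05 reads, and 226 genes with an FPKM above 0 could not be recovered. The count column was used throughout. The recovered reads and the fit without this library served as alternatives, the first of them chosen after seeing the data.

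Total counts per library ran from 14243344 to 17125440, so that 3 counts, used as the floor of detection, stand for 0.175 to 0.211 CPM (edgeR's counts scaled to library size). Floors and intervals cover counting error only. Genes were tested with edgeR 4.0.16 in R 4.3.3. Low counts were removed with filterByExpr by group, which left 14025 genes, and libraries were scaled by the trimmed mean of M values (TMM), with factors from 0.825 to 1.15. A robust quasi-likelihood model with 1 mean per group was fitted to all 9 libraries. It left 6 residual degrees of freedom, and the biological coefficient of variation was 0.320. The 3 contrasts were old control against young, old Fabp4 shRNA against old control, and old Fabp4 shRNA against young. All p-values are two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. CPM are TMM-scaled unless said otherwise, errors of fold changes are standard errors, and errors of group means are standard deviations.

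The groups, the tests, the 47 gene lists (pathways, markers of cell types, and signs of handling, RNA quality or time of day) and the rule for named genes were fixed before the data were examined. Of the lists, 45 had enough tested members. Each was tested per contrast with camera of limma 3.58.1, at its preset correlation between genes of 0.01, with adjustment over the 45 lists. The test was repeated with the correlation estimated from the data. Members were also counted after adjustment over all genes and after adjustment over the list alone. A list of 20 skeletal muscle genes was added afterwards. The rule names Fabp4, all called genes where fewer than 10 were called, and the 4 members with the smallest p of each list that was called or had 3 or more members called. Genes named outside that rule are pointed out.

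The alternatives were other scalings (DESeq2 size factors, upper quartile, none), no filter or a stricter filter on counts, DESeq2 1.42.0, limma-voom, fits to the 6 libraries compared, limma-trend on log2 FPKM with a pseudocount of 1 or 0.1, the animal numbers as a block, and leaving out each library in turn. For the overlap of contrasts that share the old control libraries, 100 data sets with no group differences were simulated. The same pipeline was run on all 10 splits of the 6 libraries of each contrast into 3 and 3. Gene symbols and positions came from GENCODE mouse release 21, in which 54409 of the 54532 identifiers were found, and 1 fixed list member (Ahsp) was not found among the symbols.

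The pipeline was tested on simulated data with known changes. For old Fabp4 shRNA against old control, with 13755 simulated genes tested, edgeR called 22.4%, 75.8% and 90.8% of genes changed by 1, 2 and 3 on the log2 scale, and 7 unchanged genes. For old control against young, with 13734 genes, the shares were 16.7%, 77.3% and 87.1%, with 5 unchanged genes called. For old Fabp4 shRNA against young, also with 13734 genes, they were 13.6%, 80.3% and 83.3%, with 11 unchanged genes called. A list shifted by 1 on the log2 scale was called by camera at the preset correlation in all 3 simulated contrasts. With an estimated correlation its adjusted p was 0.0458, 0.0250 and 0.0553 in the age, knockdown and old Fabp4 shRNA against young contrasts. No library was left out of the fits reported first. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.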

Results

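Gene expression was measured in whole liver from 3 young mice, 3 old control mice and 3 old mice given the hairpin RNA against Fabp4, a carrier protein of fatty acids found mainly in fat cells and macrophages. The series title concerns targeting this protein for healthy ageing through liver metabolism. Total counts were 14243344 to 16414852 in the young libraries, 15009727 to 15951036 in the old control libraries and 14609431 to 17125440 in the libraries labelled old Fabp4 shRNA. Albumin (Alb) took between 5.34% and 10.4% of each library's counts. Mitochondrially encoded genes took between 4.15% and 14.5%. Age and virus injection went together in both comparisons with young liver, since the labels describe no injection of the young mice.

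The targeted gene Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576, GRCm38) did not follow the labels in every library. It stood at 7.21, 13.6 and 10.9 CPM in old control replicates 1, 2 and 5, and at 11.2, 3.81 and 7.58 CPM in the libraries labelled old Fabp4 shRNA replicates 1, 3 and 6. Replicate 1 of the latter was thus above 2 of the 3 controls and replicate 6 above 1. The group means were 10.6 ± 3.21 CPM (SD, n = 3) in old control and 7.52 ± 3.68 CPM (SD, n = 3) in old Fabp4 shRNA. Their log2 difference in edgeR was -0.49 ± 1.16, with a 95% interval of -3.33 to 2.35, an unadjusted p of 0.685 and an adjusted p of 0.960. An exact two-sided permutation test of the 6 values gave p = 0.5, where 3 livers against 3 allow no p under 0.1. Without the unnumbered young library, which sets much of the spread of this gene, the log2 difference was -0.47 ± 0.38. A lower Fabp4 RNA in the livers labelled old Fabp4 shRNA was therefore not detectable, and no direction below rests on a measured knockdown. The subcutaneous fat, which was also injected, and the protein were not measured here, so a knockdown there was not examined.

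The unnumbered young library held some transcripts at far higher levels than the other libraries. Its Fabp4 was 64.8 CPM, against 3.40 and 2.67 CPM in young replicates 1 and 5. Genes of skeletal muscle fibres were present at the same time: in CPM of total counts it had 1069 for Acta1 (skeletal actin), 338 for Ckm (muscle creatine kinase) and 526 for Myh4 (a fast myosin). The highest values among the other 8 libraries were 44.5 for Acta1 and 5.84 for Ckm, both in old Fabp4 shRNA replicate 3, and 0.266 for Myh4. That replicate held other muscle transcripts as well, such as Myh1 at 13.0 against 356 in the unnumbered young library. These muscle genes were picked after their values had been seen. In the reads recovered from the FPKM column of the same name, Acta1 was 2.88 CPM, Ckm 0.678 CPM and Fabp4 2.20 CPM. The edgeR log2 fold change of Fabp4 in old control against young liver was -1.17 ± 1.15 (adjusted p = 0.756). It was 1.76 ± 0.46 (0.262) without the unnumbered young library and 1.84 ± 0.39 (0.0743) with the recovered reads. In old Fabp4 shRNA against young liver it was -1.66 ± 1.17, 1.30 ± 0.45 and 1.38 ± 0.38 in the same fits. Fabp4 was fixed beforehand, so its unadjusted edgeR p was also planned. For old control against young it was 0.344, 0.00217 and 0.000323 in these fits, in the same order. For old Fabp4 shRNA against young it was 0.198, 0.0138 and 0.00314. The direction of Fabp4 thus turned with this library, and adjusted over all genes it was called in none of these fits. Of the 14025 tested genes, 19 were at least 10 times as high in the unnumbered young library as in any other. Of these, 0 belonged to a fixed list or to the genes called by edgeR or DESeq2. That 0 decides little, since the filter removes genes present in 1 library alone, and a gene high in 1 young liver of 3 is hard to call. Ucp3 of the PPARalpha list, at 14.3 CPM of total counts in that library and at most 0.179 in the others, was not tested.

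**Figure D1:**
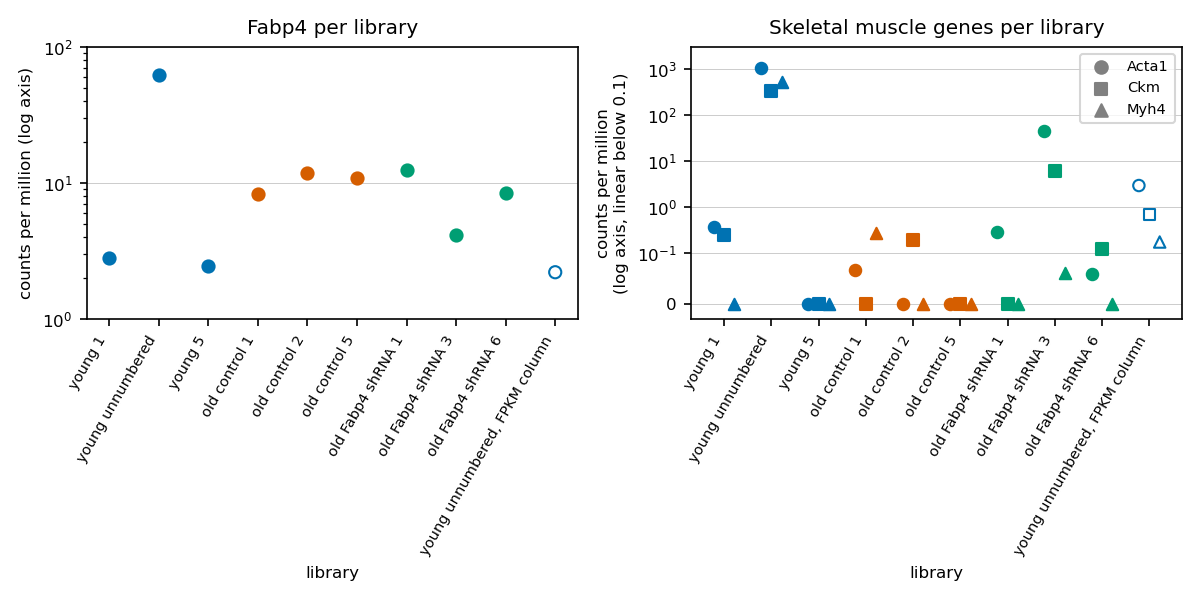
CPM of total counts in each library, on log axes (right axis linear below 0.1), for Fabp4 (left) and the skeletal muscle genes Acta1, Ckm and Myh4 (right), with young in blue, old control in orange and old Fabp4 shRNA in green. Open symbols show reads recovered from the FPKM column of the unnumbered young library, where Fabp4 is 2.20, against 62.7 in the count column of that name.

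Old control livers were compared with young livers to ask what differs with age. Noct (nocturnin, a phosphatase with a daily rhythm of expression; ENSMUSG00000023087, chromosome 3, 51224447 to 51251644) was the only called gene that is protein-coding. It averaged 206 ± 55.1 CPM in old control and 22.5 ± 7.78 CPM in young liver (SD, n = 3 each), a log2 fold change of 3.19 ± 0.40. The other called genes were also higher in old control. They were the pseudogene Gtpbp4-ps1 at 3.49 ± 0.41, the non-coding Gm40923, and Gm15401 at 4.71 ± 0.44 with its overlapping neighbour Gm37969 at 5.49 ± 0.63. Gm37969 had 213 counts in the old control livers and 4 in the young ones. Its fold change was 6.61 ± 0.76 without the unnumbered young library and 4.92 ± 0.66 with the recovered reads. Gm40923 had 217 counts in the old control livers and 2 in the young ones, a ratio of 98.4 with an exact 95% counting interval of 26.9 to 818. Reads of Gtpbp4-ps1 may be shared with related sequences. Gm15401 and Gm37969 overlap each other and Tcf7l1, and Noct overlaps Gm38357, so these values are uncertain where strand was not used in counting.

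These were 5 genes higher and 0 lower in edgeR, with adjusted p from 0.00157 to 0.0121. At an unadjusted p under 0.05 there were 901 higher and 571 lower genes, 1472 in all, where simulated data with no group differences gave 633 on average. The simulation draws each gene on its own, with no variation shared between genes. In fits to the 6 libraries alone the real split gave 1564 such genes and the highest split that mixed old and young livers 818. The 10 splits are too few for a share under 0.05. In edgeR 29, 24 and 26 of the 100 simulated sets held at least 1 called gene, and at most 3, 3 and 4, in the age, knockdown and old Fabp4 shRNA against young comparisons. DESeq2 called 109 higher and 59 lower, and limma-voom 3 higher. Without the unnumbered young library Noct, Gm15401 and Gm37969 were called. Without young replicate 1 only Gm15401 was called, and it stayed called with each of the 9 libraries left out in turn. The count was 3 with young replicate 5, old control replicate 1 or old control replicate 2 left out in turn. The call of Noct ended without young replicates 1 or 5 or old control replicates 1 or 2 (adjusted p from 0.0838 to 0.141 in edgeR), and it was kept in the other 5 fits. With old Fabp4 shRNA replicate 1 out of the fit it was 10. With the reads recovered from the FPKM column it was 10 as well, and among them Igfbp7 (1.37 ± 0.23), Adamts1 (1.95 ± 0.29) and Esm1 (3.77 ± 0.60) were higher and Dclk3 (-2.64 ± 0.44) lower. Those 4 were chosen after their values were seen.

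Of the 45 gene lists, camera called 12 higher and 9 lower in old control than in young liver at the preset correlation, and 0 with an estimated correlation, where the lowest adjusted p was 0.0804. Without the unnumbered young library 28 lists were called, and 31 with the reads recovered from the FPKM column. With the latter, red blood cell markers also passed with an estimated correlation (adjusted p = 0.0362). Among the members, 65 in 16 lists passed adjusted over the list alone. Over all genes, Noct was the only list member to pass. In a fit to the 6 libraries alone the real split gave 22 called lists, and the highest of the splits that mixed old and young livers gave 23, with 10 splits too few for a share under 0.05.

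Markers of red blood cells were lower in old control liver. All 8 tested members had negative fold changes, with a median of -1.76, and 7 passed adjusted over the list alone. They included the globin genes Hbb-bt (-2.32 ± 0.43), Hbb-bs (-1.71 ± 0.38) and Hba-a1 (-1.57 ± 0.45). Camera gave an adjusted p of 1.0e-13, and the adjusted p was 0.0804 with an estimated correlation. Nuclear genes of oxidative phosphorylation were lower in 34 of 34 members, with a median of -0.45 and 0 members called adjusted over the list alone. Examples were Ndufv1 (-0.73 ± 0.21) and Sdhb (-0.65 ± 0.22), subunits of complexes I and II. The adjusted p was 1.7e-11, and 0.284 with an estimated correlation. Genes of the urea cycle and amino acid breakdown were lower in 23 of 25, with a median of -0.42 and none passing alone, among them Sds (-1.46 ± 0.43) and Gls2 (-0.72 ± 0.25). Here the adjusted p was 4.0e-07, and 0.308 with an estimated correlation. Male-biased liver genes had a median of -0.71, which was -0.49 without the unnumbered young library and -1.18 with the recovered reads. Of 19 members 7 were lower adjusted over the list alone, such as the major urinary protein Mup21 (-1.51 ± 0.38), the steroid enzyme Hsd3b5 (-2.17 ± 0.52) and Keg1 (-1.09 ± 0.19). That adjusted p was 3.2e-07, and 0.284 with an estimated correlation.

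Markers of several non-parenchymal cell types were higher in old control liver. Liver endothelial markers were higher in 16 of 16 members, with a median of 0.71, and 7 passed adjusted over the list alone, including Clec4g (1.38 ± 0.35), Oit3 (1.25 ± 0.35) and Fcgr2b (1.38 ± 0.39). Stellate cell and fibroblast markers had a median of 0.70 with 4 of 14 passing alone, such as Pdgfra (1.30 ± 0.31) and Dcn (1.11 ± 0.27). B and plasma cell markers had a median of 0.59 with 6 of 17 passing alone, among them the immunoglobulin genes Igkc (1.89 ± 0.37) and Igha (1.58 ± 0.36). Monocyte-derived macrophage markers had a median of 1.23, with Lyz2 at 1.29 ± 0.38 and 0 passing alone. Neutrophil markers had a median of 1.17, with only Csf3r (1.52 ± 0.43) of 11 passing alone, and of 1.79 without the unnumbered young library and 2.08 with the recovered reads. Inflammatory cytokines and chemokines had a median of 0.91. Adjusted over the list alone 7 members were higher, such as Ccl2 (3.68 ± 0.77) and Cxcl16 (1.25 ± 0.36), and 1 was lower, Ccl9 (-0.75 ± 0.27), which is named after its value was seen. Ccl3 was listed at 0 in the young livers and was at least 14.5-fold higher in old control, with 3 counts over the group as the floor, and the list's median was also 0.91 with Ccl3 at that bound. Immediate early genes, which respond to handling and stress, had a median of 0.63 with Fos at 1.89 ± 0.58 and 0 passing alone, and of 0.94 without the unnumbered young library and 1.14 with the recovered reads. The adjusted p of these 7 lists ran from 1.2e-07 to 0.00156, and from 0.284 to 0.462 with an estimated correlation. All 11 lists of this and the preceding paragraph were still called without each library in turn.

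For 10 further lists the age call ended without a particular library. Interferon response genes were higher in 34 of 35 members, with a median of 0.77 and Oas3 at 2.58 ± 0.84 (adjusted p = 8.5e-07, and adjusted p = 0.517 with an estimated correlation). The call ended without old control replicate 1 (adjusted p = 0.156), in which Irf7 was 312 CPM of total counts against 50.7 or less in the other old controls. The median was 0.45 without the unnumbered young library and 0.55 with the recovered reads. Antigen presentation genes were higher, with a median of 0.28 and 3 of 20 passing adjusted over the list alone, such as H2-Ab1 (1.01 ± 0.29). That call ended without the unnumbered young library (0.101, median 0.11) and without old control replicate 1 (0.372). Extracellular matrix genes had a median of 0.36 with Bgn (1.00 ± 0.26) and 2 others passing alone, and the call ended without young replicate 1 (0.0607) or old control replicate 5 (0.0937). Their median was 0.87 without the unnumbered young library and 0.73 with the recovered reads. Cholangiocyte markers had a median of 0.46, with Sox9 at 2.01 ± 0.57, and were not called without young replicate 1 (0.0583) or old control replicate 5 (0.307). Genes of the unfolded protein response had a median of 0.49, with Derl3 at 2.90 ± 0.75 and Trib3 at -1.26 ± 0.34 passing alone in opposite directions. Leaving out young replicate 1, young replicate 5 or old control replicate 2 ended that call (0.141 to 0.855). With an estimated correlation the adjusted p of these last 4 lists was 0.530, 0.491, 0.462 and 0.648.

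Among those lower, periportal genes had a median of -0.35, with Etnppl (-1.69 ± 0.46) and Sds passing adjusted over the list alone and Apoc2 (1.24 ± 0.36) passing in the other direction. Phase II conjugation genes had a median of -0.24, with Gstp1 at -1.35 ± 0.39. Both calls ended without young replicate 1, at adjusted p of 0.0747 and 0.0957. Cytochrome P450 genes had a median of -0.17, with Cyp2c23 at -0.76 ± 0.24, and the call ended without young replicates 1 or 5 or old control replicate 1 (0.0607 to 0.377). Cholesterol synthesis genes had a median of -0.35, and the call ended without young replicates 1 or 5 or old control replicate 5 (0.0576 to 0.752). Mitochondrially encoded genes had a median of -0.22, with mt-Nd3 at -0.46 ± 0.34, and the call ended without young replicates 1 or 5, old control replicate 1 or old Fabp4 shRNA replicate 3 (0.0547 to 0.787). Without the unnumbered young library the medians of the last 3 lists were -0.37, -0.51 and -0.47, and with the recovered reads -0.32, -0.49 and -0.46. The adjusted p of these 5 lists ran from 0.451 to 0.648 with an estimated correlation.

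Genes of the circadian clock differed between libraries within groups. Dbp, an output gene of the clock, was 100 and 90.1 CPM in young replicates 1 and 5 and 32.4 CPM in the unnumbered young library. It was 0.581, 0.589 and 16.4 CPM in old control replicates 1, 2 and 5, and 53.5, 0.496 and 4.86 CPM in old Fabp4 shRNA replicates 1, 3 and 6. Over the list of 20, 3 members were higher and 4 lower in old control than in young liver adjusted over the list alone, and 1 (Noct) passed over all genes. Bhlhe41 was at -2.58 ± 0.64. The list itself was not called in that comparison (median -0.61, adjusted p = 0.0968, and adjusted p = 0.474 with an estimated correlation). It was called lower without the unnumbered young library (median -0.89, adjusted p = 0.0310), and with the recovered reads it was not (-0.75, 0.143). With an estimated correlation the adjusted p was 0.315 and 0.433 in these fits.

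**Figure D2:**
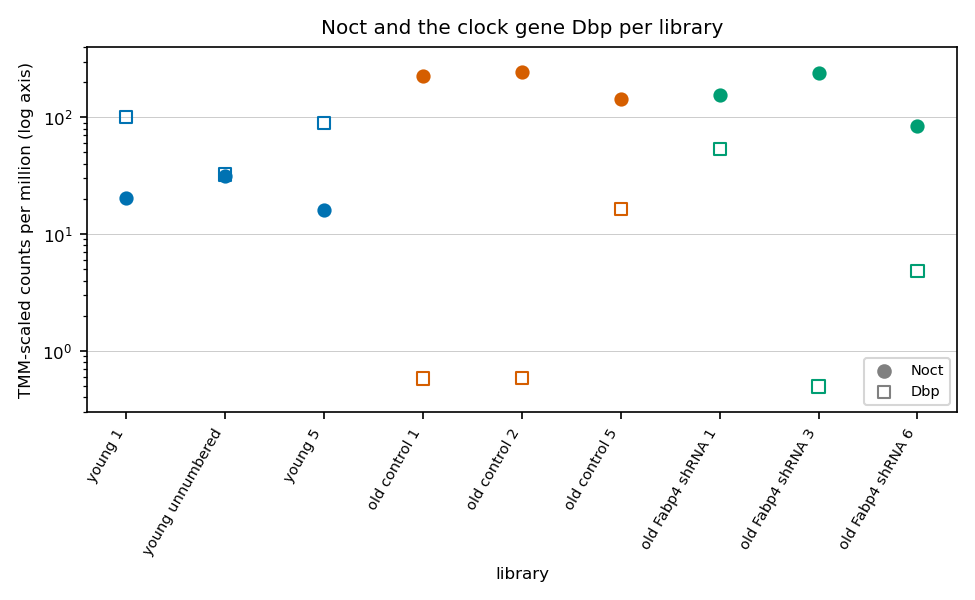
TMM-scaled CPM of Noct (filled circles) and Dbp (open squares) in each library, on a log axis, with young in blue, old control in orange and old Fabp4 shRNA in green. Noct lies between 84.3 and 246 in the 6 old libraries and between 16.1 and 31.2 in the 3 young ones, while Dbp differs widely within both old groups.

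Livers labelled old Fabp4 shRNA were compared with old control livers to ask what the hairpin RNA changed, with the reservation that Fabp4 in 2 of them, replicates 1 and 6, lay within the range of the controls. No gene passed edgeR's test. The genes with the smallest p were A2ml1, a protease inhibitor, at -1.43 ± 0.24 (10.7 ± 3.65 against 28.8 ± 2.08 CPM, SD, n = 3 each), Cib3 at -3.44 ± 0.57 and Akr1c19, an aldo-keto reductase, at 1.23 ± 0.23. Also among the 5 with the smallest p was Spp1 (osteopontin) at -1.77 ± 0.36, with 25.2 ± 8.36 against 86.1 ± 48.8 CPM. These genes were named after their values had been seen.

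In edgeR 0 genes were called, the lowest adjusted p was 0.427, and 458 genes were higher and 488 lower at an unadjusted p under 0.05, 946 in all against 631 on average in the simulated data. In fits to the 6 libraries alone the real split gave 876 such genes and the highest mixed split 2034. The excess over the simulation therefore does not show a difference between these groups. DESeq2 called 7, with Akr1c19 higher and Cib3, A2ml1, Spp1, Cxcl1, mt-Tw and Ngp lower, and limma-voom called 0. Without old Fabp4 shRNA replicate 1 edgeR called 1 gene, A2ml1 at -1.74 ± 0.23 (adjusted p = 0.0371), and with any other library left out 0. With 3 livers in each group, the simulated data gave calls for 75.8% of genes changed by 2 on the log2 scale in this comparison. That share holds with 67, 66 and 65 tested genes changed by 1, 2 and 3 at once, and each gene drawn on its own. It may be lower where few genes change, since the adjustment is then stricter, and Cib3 at -3.44 ± 0.57 was not called here.

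Camera called 4 lists higher and 14 lower in the livers labelled old Fabp4 shRNA than in old control at the preset correlation, and 0 with an estimated correlation. For the called lists the adjusted p was 0.453 to 0.670 with an estimated correlation. In a fit to the 6 libraries alone the real split gave 18, and the highest of the mixed splits gave 25, with 10 splits too few for a share under 0.05. Adjusted over the list alone 14 members in 7 lists passed, and 0 did over all genes. Directions here are those of the livers as labelled, and 6 of the 18 lists were still called without each library in turn.

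Neutrophil markers were lower by the largest median, -2.33, with 10 of 11 members lower and 8 passing adjusted over the list alone. Among these were the granule genes Elane (-2.84 ± 0.66), Ngp (-3.73 ± 0.91) and Camp (-4.03 ± 1.10). Their levels were low, with Elane at 1.54 ± 0.65 CPM in old control and 0.210 ± 0.101 CPM in old Fabp4 shRNA. The latter lies near the floor of 3 counts, so the size of the fold change of Elane is uncertain. For the neutrophil list the adjusted p was 1.9e-15, and 0.453 with an estimated correlation. Inflammatory cytokines and chemokines were lower in 22 of 23 members, with a median of -0.66, Vcam1 at -0.96 ± 0.28 and 0 passing alone. Monocyte-derived macrophage markers were lower in 14 of 15, with a median of -0.69 and Cd68 at -1.11 ± 0.38, 0 passing alone. Cholangiocyte markers were lower in 12 of 12, with a median of -0.89, and only Spp1 passed alone. For these 3 lists the adjusted p was 6.8e-07, 3.9e-05 and 2.4e-06, and it was 0.478, 0.478 and 0.453 with an estimated correlation. Mitochondrially encoded genes were lower in 12 of 13, with a median of -1.14 and mt-Nd3 (-1.34 ± 0.35) passing alone, at an adjusted p of 3.7e-07, and 0.478 with an estimated correlation. That list was fixed among the signs of handling, RNA quality or time of day. Of all counts, such genes took 4.42%, 11.1% and 14.5% in old control replicates 1, 2 and 5. They took 8.47%, 4.15% and 4.22% in old Fabp4 shRNA replicates 1, 3 and 6, so the groups overlapped. Fatty acid oxidation genes were higher in 23 of 24, with a median of 0.39. The peroxisomal thiolase Acaa1b (1.19 ± 0.31) passed alone, and Acadvl (1.59 ± 0.58) and Hadha (0.89 ± 0.35) did not. That adjusted p was 6.8e-07, and 0.478 with an estimated correlation.

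Other lists were called in this comparison with all libraries and not without a particular library. Interferon response genes were lower in 34 of 35, with a median of -0.86 and Ifi47 at -0.89 ± 0.24, and the call ended without old control replicate 1 (adjusted p = 0.113, and with an estimated correlation 0.558). Without the same library, antigen presentation (median -0.44, H2-Ab1 at -0.82 ± 0.29), cholesterol synthesis (median -0.28, Sqle at -1.36 ± 0.40) and PPARalpha target genes (median 0.36, Acot1 at 1.51 ± 0.54) were not called either. Their adjusted p was then 0.0743, 0.0950 and 0.0910, and with all libraries and an estimated correlation it was 0.478, 0.670 and 0.478. Kupffer cell markers (median -0.99, Csf1r at -1.05 ± 0.40) were not called without old control replicate 1 (0.675) or old Fabp4 shRNA replicate 3 (0.0752), and had an adjusted p of 0.658 with an estimated correlation. B and plasma cell markers (median -0.45) included Igha at -1.54 ± 0.36, which passed adjusted over the list alone, and were not called without old control replicate 5 (0.364) or old Fabp4 shRNA replicate 3 (0.266). Their adjusted p was 0.558 with an estimated correlation.

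Periportal genes (median -0.35, Arg1 at -0.92 ± 0.33) lost their call without old Fabp4 shRNA replicate 1 (adjusted p = 0.0803). Without old Fabp4 shRNA replicate 1 or old control replicates 1 or 2, neither complement and acute phase genes (median -0.51, Cp at -1.04 ± 0.35) nor pericentral genes (median 0.29, Glul at 0.76 ± 0.34) were called (0.0586 to 0.658). Hepatocyte markers (median -0.33, Apoa1 at -0.79 ± 0.29) were not called without old control replicate 2 (0.286) or old Fabp4 shRNA replicate 1 (0.0879). Extracellular matrix genes (median -0.43, with Spp1 alone passing within the list) were not called without old control replicate 5 or old Fabp4 shRNA replicates 1 or 6 (0.0599 to 0.336). Circadian clock genes (median 0.45, Usp2 at 2.98 ± 0.98) were called with all libraries at an adjusted p of 0.0482, and 7 of the 9 fits without a library did not call them (0.0516 to 0.538). Those 2 that did were without old control replicate 5 and without old Fabp4 shRNA replicate 6. For the lists of this paragraph the adjusted p was 0.478 to 0.670 with an estimated correlation.

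**Figure D3:**
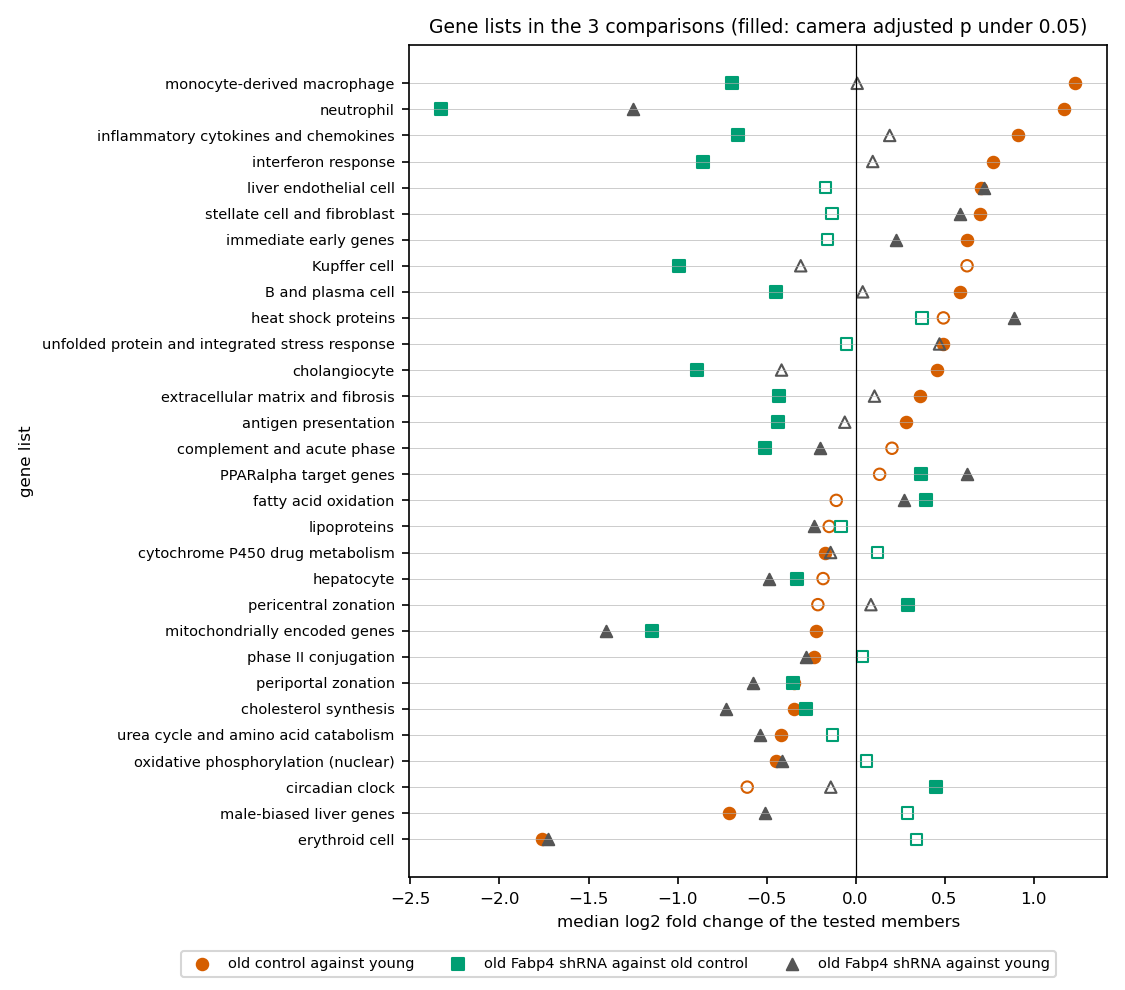
Median log2 fold change of the tested members of each gene list that camera called in any comparison (horizontal axis), for old control against young (orange circles), old Fabp4 shRNA against old control (green squares) and old Fabp4 shRNA against young (grey triangles). Filled symbols mark an adjusted p under 0.05 at the preset correlation, and with an estimated correlation 0 lists were called in any comparison.

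Livers labelled old Fabp4 shRNA were last compared with young livers, to ask which differences from young remained in them. Noct was again higher, at 160 ± 77.8 against 22.5 ± 7.78 CPM (SD, n = 3 each) and a log2 fold change of 2.83 ± 0.40. Tceal8, a member of a family of transcription elongation factor-like proteins on chromosome X, was lower at 4.91 ± 1.57 against 22.0 ± 0.894 CPM, a log2 fold change of -2.16 ± 0.30. Dmrta1 was higher at 3.22 ± 0.47, as was the immunoglobulin segment Igkv3-2 at 4.20 ± 0.65. Gm15401 (3.74 ± 0.44), Gm37969 (4.14 ± 0.64), Gtpbp4-ps1 (3.49 ± 0.41) and Gm40923 were also higher, with the uncertainty of overlapping or related sequences stated above. Gm40923 had 139 counts against 2, a ratio of 54.8 with an exact 95% counting interval of 14.9 to 457. Gm37969 had 95 counts against 4. Its fold change was 5.30 ± 0.79 without the unnumbered young library and 3.60 ± 0.68 with the recovered reads.

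These were 7 genes higher and 1 lower in edgeR, with adjusted p from 0.0142 to 0.0408, and 622 higher and 631 lower at an unadjusted p under 0.05, 1253 in all against 631 on average in the simulated data. In fits to the 6 libraries alone the real split gave 1011 genes at that threshold and the highest mixed split 2914. An excess over the simulation thus does not show a difference between these groups. DESeq2 called 51 higher and 73 lower, and limma-voom 0. The count depended on single libraries. It was 0 without young replicate 1, 3 without young replicate 5, between 2 and 5 with each old control and old Fabp4 shRNA replicates 3 and 6 left out in turn, and 37 without old Fabp4 shRNA replicate 1. It was 6 without the unnumbered young library, and Tceal8 (adjusted p = 0.0575), Dmrta1 (0.0811), Igkv3-2 (0.0896) and Gm40923 (0.0827) were not among them. Of the 9 fits with a library left out, Gm15401 was still called in 8, Gtpbp4-ps1 in 7, Noct, Tceal8 and Gm40923 in 3 each, Gm37969 in 2, and Dmrta1 and Igkv3-2 in 1 each. A fit to the 6 libraries alone called 0. With the reads recovered from the FPKM column there were 33 higher and 29 lower. Among those, chosen after their values were seen, the urea cycle gene Otc (-1.50 ± 0.26), the globin gene Hba-a1 (-2.14 ± 0.35) and Mup21 (-2.41 ± 0.41) were lower.

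Camera called 6 lists higher and 12 lower than in young liver at the preset correlation and 0 with an estimated correlation, where the lowest adjusted p was 0.168. Both without the unnumbered young library and with the recovered reads 21 lists were called, among them extracellular matrix genes, whose median was 0.61 and 0.48 in place of 0.11 (adjusted p = 0.000741 and 0.00204, and 0.459 and 0.467 with an estimated correlation). In a fit to the 6 libraries alone the real split gave 17, and the highest of the mixed splits gave 19, with 10 splits too few for a share under 0.05. Adjusted over the list alone 51 members in 15 lists passed, and over all genes only Noct. Mitochondrially encoded genes were lower in 13 of 13 members, with a median of -1.40 and 5 passing alone, such as mt-Nd3 (-1.80 ± 0.36) and mt-Co2 (-1.43 ± 0.42). Their share of all counts was 13.8% and 11.4% in young replicates 1 and 5 and 6.89% in the unnumbered young library. Old Fabp4 shRNA replicate 1, at 8.47%, lay within that range. Red blood cell markers were lower in 8 of 8, with a median of -1.73 and 6 passing alone, such as Hbb-bt (-1.76 ± 0.42). Urea cycle and amino acid genes had a median of -0.54 with 7 of 25 passing alone, among them Otc (-1.24 ± 0.26) and Sds (-1.91 ± 0.44). Periportal genes, which share Sds and Gls2 with that list, had a median of -0.57 with 8 of 18 passing alone. Cholesterol synthesis genes had a median of -0.73 (-1.10 without the unnumbered young library and -0.80 with the recovered reads) with 5 of 25 passing alone, such as Lss (-1.10 ± 0.31) and Sqle (-1.39 ± 0.40). Male-biased genes had a median of -0.51, with 4 lower, such as Mup21 (-1.99 ± 0.39), and 2 higher, such as Mup7 (1.51 ± 0.37), adjusted over the list alone. The adjusted p of these 6 lists ran from 2.2e-11 to 7.8e-05, and from 0.168 to 0.470 with an estimated correlation.

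Nuclear oxidative phosphorylation genes (median -0.41, Sdhb at -0.87 ± 0.22), hepatocyte markers (median -0.49, Ahsg at -0.89 ± 0.30) and phase II genes (median -0.28, Tpmt at -0.95 ± 0.24) were lower with 0 members passing alone. With no composition factors the phase II median was 0.01. Higher were PPARalpha target genes (median 0.63, and 0.98 without the unnumbered young library and 1.10 with the recovered reads), of which the thioesterases Acot1 (2.21 ± 0.56) and Acot4 (1.01 ± 0.28) passed alone. Fatty acid oxidation genes (median 0.27, 0.46 with the recovered reads, Acaa1b at 0.98 ± 0.31), heat shock proteins (median 0.89, Hspb1 at 1.86 ± 0.60) and stellate cell markers (median 0.59, Dcn at 0.87 ± 0.27) were also higher with 0 passing alone. For these 7 lists the adjusted p was 1.3e-08 to 0.00189, and 0.243 to 0.611 with an estimated correlation. All 13 lists named so far for this comparison were still called without each library in turn.

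Liver endothelial markers were higher (median 0.72, with Oit3 at 1.26 ± 0.35 among 3 of 16 passing adjusted over the list alone), and were not called without old Fabp4 shRNA replicate 1 (adjusted p = 0.0546). Immediate early genes were higher (median 0.23, Fos at 1.74 ± 0.57), and were not called without young replicates 1 or 5 or old Fabp4 shRNA replicates 3 or 6 (0.115 to 0.488). Their median was 0.73 without the unnumbered young library and 0.86 with the recovered reads. Neutrophil markers were lower (median -1.25, Ngp at -3.00 ± 0.92), and were not called without the unnumbered young library (0.0574) or old Fabp4 shRNA replicate 1 (0.0572). Their median was -0.41 without the unnumbered young library and -0.04 with the recovered reads (adjusted p = 0.408). Complement and acute phase genes were lower (median -0.20, with Mt2 at -2.76 ± 0.66 passing alone), and were not called without the unnumbered young library (0.215, median -0.02), with the recovered reads (0.274, median 0.03) or without old Fabp4 shRNA replicate 1 (0.972). Lipoprotein genes were lower (median -0.24), and were not called without young replicate 1 (0.0696) or old Fabp4 shRNA replicate 1 (0.0772). With no composition factors the medians of the last 2 lists were 0.09 and 0.06, and with the recovered reads that of the lipoprotein genes was -0.08. With an estimated correlation the adjusted p of these 5 lists ran from 0.243 to 0.776.

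The first 2 comparisons were then set side by side to ask whether genes that differ with age moved back in the livers labelled old Fabp4 shRNA. In edgeR 0 genes were called in both in opposite directions and 0 in the same direction, where the product of both counts over the genes tested is 0. With 0 genes called in the knockdown comparison, these counts could only be 0 and decide nothing. At an unadjusted p under 0.05 in both, 279 genes had opposite directions and 4 the same. Simulated data with no group differences gave on average 137 and 1.28, because the same old control libraries enter both comparisons. The counts were 201 and 18 without the unnumbered young library, and 268 and 28 with the recovered reads. Across the 14025 genes, which are not independent replicates, the fold changes had a correlation of -0.44, against a simulated mean of -0.50 (-0.53 to -0.48), and a covariance of -0.141, against a simulated mean of -0.104 (-0.115 to -0.0969). The correlation was thus no stronger than shared controls alone gave, while the covariance lay -0.0367 beyond its simulated mean. Without the unnumbered young library the correlation was -0.31 and the covariance -0.122. With the recovered reads they were -0.34 and -0.110. Simulations matched to these fits, added after the data were seen, gave mean correlations of -0.44 and -0.50 and mean covariances of -0.101 (-0.112 to -0.0922) and -0.0882 (-0.0953 to -0.0817). Their mean counts of opposite directions were 120 and 131, and of the same direction 1.87 and 1.17. The 3 old control libraries cannot be split into independent parts of 2 or more, so part of any excess may come from the shared controls. The simulations also drew each gene on its own, so their ranges hold no variation shared between genes.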

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

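All settings here were planned except the reads recovered from the FPKM column, which were chosen after the data were seen. Other scalings (RLE, upper quartile, none) and the stricter filter left each count of called genes within 1.5 times its value. The medians of 3 called lists in old Fabp4 shRNA against young changed sign with no composition factors. With no composition factors the median of all genes moved by 0.146, 0.140 and 0.286 in the age, knockdown and old Fabp4 shRNA against young comparisons.

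Called genes in old control against young liver were 5 as reported. There were 137 with no filter on low counts, 168 in DESeq2, 3 in limma-voom, 15 with only the 6 libraries compared, 18 and 21 with limma-trend on log2 FPKM plus 1 and plus 0.1, 2 with that and no filter, 10 with recovered reads, and 1 (without young replicate 1) to 10 (without old Fabp4 shRNA replicate 1) with a library left out. For old Fabp4 shRNA against old control the 0 became 8 with no filter, 7 in DESeq2, 1 with each FPKM pseudocount, and 0 to 1 (without old Fabp4 shRNA replicate 1) with a library left out. For old Fabp4 shRNA against young the 8 became 94 with no filter, 124 in DESeq2, 0 in limma-voom and with only the 6 libraries compared, 53 and 77 with FPKM plus 1 and plus 0.1, 0 with FPKM and no filter, 62 with recovered reads, and 0 (without young replicate 1) to 37 (without old Fabp4 shRNA replicate 1) with a library left out. The FPKM settings change the unnumbered young library as well as the unit. Genes called in opposite directions in the age and knockdown comparisons went from 0 to 2 with no filter and to 1 in DESeq2, and stayed at 0 with each library left out. That last 0 decides little, since the knockdown comparison had only 0 to 1 called genes in those fits. Called lists went from 21, 18 and 18 to 0 in each comparison with an estimated correlation, and to 31, 17 and 21 with recovered reads. With a library left out they were 13 (without young replicate 1) to 28, 12 to 21, and 16 to 21. The cause was not tested for any of these.

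No label says that the animal numbers pair the libraries. Libraries with the same number correlated across genes by 0.133, 0.0988, 0.0566 and -0.0507. Of the 5 libraries with a same-numbered partner in another group 2 matched it best, young replicate 1 and old control replicate 1. These few values give little sign of a pairing and cannot exclude it. A block by number gave 158, 73 and 23 called genes, 30 in opposite directions, and Fabp4 at 0.42 ± 0.40 in the knockdown comparison in place of -0.49. Only the numbers 1 and 5 recur across groups, and each library with another number or none was absorbed by its own block. In the old Fabp4 shRNA group the block fit thus rested on replicate 1 alone. Fabp4 in that library was 11.2 CPM, against 7.21 CPM in old control replicate 1. The counts of this fit are therefore not those of 3 livers against 3, and the cause of their size was not tested. With a library left out, Fabp4 lay between -0.88 and -0.17 and the correlation across genes between -0.62 and -0.31. With 1 library of 3 left out, the remaining pair is assumed to vary like the other groups. Of 236 results for named genes, DESeq2 newly called 47 and limma-voom lost 10. At 14243344 to 17125440 counts a library, the floor of 3 counts lies at 0.175 to 0.211 CPM, depending on the library.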

Other observations

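Of the pattern tests below, the position of the unnumbered library between young and old and the lists called in other splits were set before their results were seen. The tests of fat, muscle, the paired tables and an old liver by Fabp4 or by called genes, of Noct and the clock, of blood cells, and of genes called in other splits were chosen only after the results were seen.

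Several lists that camera did not call with all libraries held members that passed adjusted over the list alone in old control against young liver. In the lipid droplet list (adjusted p = 0.710, median 0.04) G0s2, an inhibitor of fat breakdown, was higher by 1.93 ± 0.44. In the sirtuin and NAD list (adjusted p = 0.177, median -0.19) Cd38, an enzyme that consumes NAD, was higher by 1.30 ± 0.34. In the senescence list (adjusted p = 0.143, median 0.26) 2 members were higher and 2 lower, with Igfbp7 at 1.29 ± 0.24 and Igfbp5 at -1.76 ± 0.52. In the list of fetal and liver tumour genes (adjusted p = 0.416, median 0.05) Sox9 was higher by 2.01 ± 0.57. The median of that list was 0.45 without the unnumbered young library and 0.29 with the recovered reads. For the lipid droplet list these medians were 0.25 and 0.22. Fatty acid oxidation genes, which were higher in the livers labelled old Fabp4 shRNA, had a median of -0.11 in old control against young liver (adjusted p = 0.434). Their median was 0.06 without the unnumbered young library and 0.13 with the recovered reads, and neither fit called the list. With an estimated correlation the adjusted p of these 5 lists ran from 0.498 to 0.890. The senescence list was called without the unnumbered young library (adjusted p = 0.00255, median 0.56) and with the recovered reads (0.00652), as was the sirtuin and NAD list (0.0447 and 0.0370), and the lipid droplet list only with the recovered reads (0.0173). Those adjusted p ran from 0.277 to 0.412 with an estimated correlation. Except for Sox9, which the rule names in the cholangiocyte list, these genes are outside the rule for naming and were chosen after their values were seen.

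In old Fabp4 shRNA against old control liver, lists of lipogenesis (median -0.02), bile acids (0.01), glucose metabolism (0.02), antioxidant genes (0.02), insulin and IGF (-0.04), cell cycle (-0.17) and T and NK cells (-0.06) were not called, with adjusted p from 0.427 to 0.880. The lipoprotein list was not called either (adjusted p = 0.104, but 0.0438 without the unnumbered young library, and 0.530 there with an estimated correlation), though Pltp, a phospholipid transfer protein, passed adjusted over the list alone at -1.13 ± 0.27. The heart muscle gene Myh6 had 0 counts in all 9 libraries, while Myh7, shared by heart and slow skeletal muscle, was 42.7 CPM of total counts in the unnumbered young library and 0 in the other 8. The highest pancreatic transcript was Cela1 at 19.2 CPM.

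For the high Fabp4 of the unnumbered young library (64.8 CPM) fat tissue is argued against, since the higher of Adipoq and Plin1 was 0.0618 CPM there. An old liver under a young name would not by itself account for this level, since the 6 old libraries had at most 13.6 CPM of Fabp4. The level does not tell the age of the liver, since young replicates 1 and 5 were lower still, at 3.40 and 2.67 CPM. At 3 of 3 genes called without the unnumbered library (Noct and the overlapping Gm15401 and Gm37969) that library lay on the young side of all 6 old ones. At these few genes that argues against a liver like the 6 injected old ones. It does not tell the age of the liver, since age and injection go together in these genes and Noct may follow the time of day. A position of 49.0 on a scale from 0 for young to 100 for old did not decide its age either, since young replicates 1 and 5 lay at 51.3 and 55.7 and old Fabp4 shRNA replicate 1 at 39.2. Skeletal muscle in the sample is a candidate source, since 19 of 20 muscle genes were at least 10 times as high as in any other library, although the Fabp4 that muscle brings was not measured, and no biological explanation was tested. The FPKM column of the same name comes from another library, as only 0.229% of its genes were a fixed multiple of the count, and that library had neither the high muscle transcripts nor the high Fabp4.

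Noct in old liver may reflect the time of day at collection, which the labels do not give, as well as age or injection. A clock score (the main axis of the other circadian genes, 84.6% of their variance) as a covariate lowered the old control against young fold change from 3.19 ± 0.40 to 2.65 ± 0.49, and the edgeR call ended with an adjusted p of 0.0560 as the fold fell and its error grew. In old Fabp4 shRNA against young liver it was 2.53 ± 0.39 with the covariate, at an adjusted p of 0.0430, and the fit called 45, 8 and 16 genes in place of 5, 0 and 8 in the age, knockdown and old Fabp4 shRNA against young comparisons, without Gtpbp4-ps1 (0.0656 and 0.0533 in the comparisons with young). Over the 6 old libraries log2 Noct and the score had r = -0.47 (exact permutation p = 0.378) and rho = -0.77 (exact permutation p = 0.103), while r = -0.998 on the 4 libraries left without the 2 farthest from the median score decides nothing, as 3 of the 4 nearly coincide. Time of day and age cannot be told apart here, since old Fabp4 shRNA replicate 1, at 0.424, was the only old library with a score above the lowest young one (0.176). Noct was 157 CPM in that replicate, against 16.1 to 31.2 CPM in the young libraries, but 1 liver does not decide the question.

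Neutrophil markers were lower in the livers labelled old Fabp4 shRNA than in old control, with a median of -2.33 and a median absolute deviation of 0.514. Less residual blood is argued against, since red cell markers had a median of 0.34 with a deviation of 0.179 and 5 of 8 were higher. A loss of white blood cells of every kind alike is also argued against, since T and NK cell markers had a median of -0.0562 with a deviation of 0.410, while B and plasma cell (-0.45, deviation 0.286), monocyte-derived macrophage (-0.69, 0.361) and Kupffer cell markers (-0.99, 0.288) were lower by less than the neutrophil markers. Per library, the median neutrophil marker, as log2(CPM + 1) centred over all libraries, was 1.10, 0.929 and -0.0311 in old control replicates 1, 2 and 5. It was -0.564, -0.633 and -0.0806 in old Fabp4 shRNA replicates 1, 3 and 6. Old control replicate 5 thus lay close to old Fabp4 shRNA replicate 6. A difference in neutrophils or their precursors, or an uneven one over several immune cell types, stays open as a hypothesis for these 6 livers. Whether it goes with a lower Fabp4 could not be examined, as Fabp4 in liver was not detectably lower. Whether it follows the hairpin RNA is not settled by these 6 livers. With an estimated correlation the call of this list was not kept (adjusted p = 0.453).

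Every split of 6 libraries into 3 and 3 was also run, and 10 splits are too few for a share under 0.05. For old control against young, 1 of the 10 splits, the real one, called as many as 15 genes and the highest other called 0. For old Fabp4 shRNA against old control the real split called 0 and the highest other 5. With a real count of 0, any split calls as many, so the 10 of 10 that did decide nothing. For old Fabp4 shRNA against young the real split also called 0, with the same void 10 of 10, and the highest other called 273. That split set young replicates 1 and 5 with old Fabp4 shRNA replicate 1 apart from the rest. It points to a structure of the samples other than the groups, and it parts libraries with a clock score of at least 0.372 from those with at most 0.176. Among its genes, 4 of 20 clock genes, 6 of 35 interferon genes and 3 of 24 cholesterol synthesis genes were called. These lists were picked after their counts were seen, with no test, and phase II conjugation, for example, had 6 of 34. The clock score is itself built from genes of the clock list. Called lists numbered 22 in the real age split and 23 in the highest other, with 2 of 10 as high. They numbered 18 and 25 for old Fabp4 shRNA against old control, with 5 of 10 as high, and 17 and 19 for old Fabp4 shRNA against young, with 2 of 10 as high.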
